A study of Mus musculus with 8 samples.

How the data were processed

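The data were 8 lists of H3K27ac peaks, 1 per library, from mouse primary neuronal cultures in 4 groups of 2 libraries. Titles name the cultures CTX or MGE and the treatment KCl or unstimulated, and each group has libraries numbered 1 and 2, called biological replicates without a statement of what was kept separate. The p-values of tests that relabel libraries therefore measure only the spread between these libraries, which may be partly technical. Those of tests that count genes take the calls as given and hold no spread between libraries. Per the labels' protocols, neurons were silenced overnight on day 6 in vitro with 1 µM tetrodotoxin (TTX, a sodium channel blocker) and 100 µM D-AP5 (an NMDA receptor blocker). On day 7 they were depolarised with 55 mM KCl for 2 h or not treated. Chromatin was fixed with 1% formaldehyde and precipitated with the antibody ab4729, and reads were 50 bp long. The labels disagree on the material: titles of the CTX libraries give embryonic day 14, the source of all libraries is embryonic day 16, and the cell type field says cortical neurons for the MGE libraries too. Groups were taken from the titles.

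Per the submitters' processing notes, the tools were cutadapt 1.18, Bowtie2 2.3.3, MACS3 3.0.0a7 and deepTools 3.4.3 and the build was mm10. The role and settings of each tool, the use of an input control and the treatment of duplicate reads are not given in the sources used here. The lists are in broad-peak format, were called separately in each library, and carry the word unfiltered in their peak names. Each peak has a fold enrichment, a linear ratio as the authors deposited it, and a −log10 p and a −log10 q value, also deposited by the authors. These belong to the peak, and they were used here only to describe, rank or filter peaks within a list. The lowest −log10 q in a list lay between 1.30 and 1.35, close to a q of 0.05. Read counts were not used here, so the depth behind each list is unknown. The lists held 36035 to 66827 peaks and covered 21.1 to 44.7 Mb. A library with more reads yields more peaks, and a region just under the caller's threshold is missing from a list, so absence from a list is not absence of acetylation.

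Chromosomes 1 to 19 and X were divided into bins of 500 bp, and a bin counted as called in a library when at least 50% of it lay in peaks. The 29 peaks on other chromosomes were left out. A gained region was a run of at least 2 adjacent bins called in both KCl libraries of a culture and in neither unstimulated library, and a lost region the reverse. MGE-only and CTX-only regions were called in all 4 libraries of one culture and in none of the other. A peak of the other group may still touch a region where it fills less than 50% of each bin. With 2 libraries against 2 the smallest two-sided exact p is 0.33, so no region was tested singly, and counts were set against the other 2 ways of splitting the 4 libraries of a culture. For 4 against 4 libraries the smallest exact p is 0.029, and all 35 splits were counted. Sharing of gained bins between cultures was compared with the product expected from independent lists, with a standard error from leaving out each chromosome in turn.

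Regions went to the protein-coding gene with the nearest gene span up to 100 kb away, and to the shorter gene where spans overlapped, among 21631 genes of the assembly GRCm38.p6, whose coordinates are those of mm10. The plan had named transcript starts, exons and introns. The gene table used here gives spans without strand or transcripts, so distance to the span replaced distance to the transcript start, and location was classed as within 2 kb of either gene end, elsewhere in a gene or outside genes. Planned motif tests were not run, as no genome sequence was used here. For each of 15 gene lists, the number of genes with a region was compared with 10000 random lists matched in deciles of callable bins (called in at least 1 of the compared libraries), with at least 4 callable bins per gene. This permutation test was one-sided for more genes, with Benjamini-Hochberg adjustment over lists, cultures and directions, and 0.0001 is the smallest p it can give. Differences between cultures in listed genes with gained regions were tested with the exact two-sided McNemar test. The lists held immediate early genes, late activity-regulated genes, candidates for activity regulation in GABAergic neurons, MGE and GABAergic identity, cortical glutamatergic identity, markers of CGE interneurons, LGE and striatum, astrocytes, the oligodendrocyte lineage, microglia, endothelial and mural cells and neural progenitors, synaptic and channel genes, housekeeping genes and genes silent in neurons.

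Lists, regions, tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule names, per KCl comparison, the 10 genes with most gained bins and the 5 with most lost bins (each above the control splits), up to 10 members of the activity lists, and always Fos, Npas4, Bdnf, Igf1, Nptx2 and Scg2. For MGE against CTX it takes the 8 genes with most bins in each direction and up to 6 members of each identity list, and for the shared response the 8 genes with most bins, with ties in alphabetical order. A further measure was chosen after seeing the data: called bases within listed genes and 2 kb to each side, per Mb called in the library. It was compared between cultures with the exact two-sided permutation test and between treatments with an exact test that relabels libraries within each culture, each adjusted over the 15 lists. For a named gene, the called length is the sum in kb over all bins assigned to it, given as mean ± SD. Such a sum moves with the bases called in the library.

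Alternatives were peaks with a −log10 q of at least 5, the same number of peaks in every library (the strongest by −log10 p), bins of 1 kb, any overlap of 1 bp, merged peaks in place of bins, leaving out each library, the replicate number as a block, other rules of gene assignment, and, added after seeing the data, the same number of called bases in every library. The region and list steps were tested on simulated data. All 200 peaks of 750 to 2000 bp implanted into the CTX lists and all 200 implanted into the MGE lists were recovered as gained regions among 5257556 bins. Such widths fill 2 bins nearly by construction, so this checks the code and not the sensitivity. Widths were then drawn at random from the real lists, whose medians are 464 to 530 bp, separately for each KCl library. Of these implants 13.5% of 200 were recovered in CTX and 17.5% of 200 in MGE, so the rule missed most of them. Recovery of peaks with related widths in both libraries was not measured. Of 200 random lists of 25 genes, 1.5% had a p under 0.05 in CTX (7852 genes) and 2.5% in MGE (5994 genes), so the test was stricter than its nominal level. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.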

Results

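H3K27ac, an acetylation of histone H3 found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in mouse neuronal cultures. The design asks where acetylation changes when silenced neurons are depolarised with KCl for 2 h, a standard way to switch on activity-regulated genes. It was done in cultures titled CTX and in cultures titled MGE, a name commonly used for the medial ganglionic eminence, where many GABAergic interneurons of the cortex arise. The series title places the work in the study of experience-dependent enhancers of GABAergic neurons. There were 4 groups of 2 libraries. Peaks numbered 45059 and 66827 in CTX KCl, 41537 and 64878 in CTX unstimulated, 36035 and 49635 in MGE KCl, and 38411 and 36241 in MGE unstimulated cultures. They covered 28.4 and 44.7, 23.5 and 43.0, 21.5 and 32.0, and 23.0 and 21.1 Mb in the same order. Read depth is unknown. Libraries of the same culture and treatment shared a mean of 49.6% of the bins called in either, libraries of the same culture and the other treatment 43.6%, and libraries of different cultures 31.8% with the same and 28.6% with the other treatment.

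In CTX cultures, 386 regions were gained with KCl and 231 were lost. Immediate early genes, which neurons switch on within minutes of activity, had gained regions at 6 of the 27 tested members, against 0.914 in matched random lists (one-sided permutation p = 0.0002, adjusted p = 0.006). The 6 were Fos and Atf3, which encode bZIP transcription factors, the neuron-specific factor Npas4, the orphan nuclear receptors Nr4a2 and Nr4a3, and the kinase gene Sik1. Regions called in replicate 2 alone lay at 1 of these 27 genes, Sik1, against 1.43 in random lists. Bins assigned to Fos held 9.20 ± 1.39 kb of peaks with KCl and 3.93 ± 0.902 kb without (SD, n = 2, as for all values per gene below). At Npas4 the called length was 3.89 ± 0.645 and 2.11 ± 0.348 kb, at Atf3 2.76 ± 0.0905 and 0.729 ± 0.275 kb, at Nr4a3 4.04 ± 1.12 and 1.45 ± 0.484 kb, at Nr4a2 3.37 ± 1.09 and 2.09 ± 0.749 kb, and at Sik1 9.02 ± 2.07 and 8.04 ± 4.37 kb. Fos had a gained region on chromosome 12 at 85472501 to 85473500, 0.4 kb below the lower end of the gene span. A further region lay at 85486501 to 85488000, 9.2 kb above the upper end. Peaks of unstimulated CTX libraries touched both, from replicate 2 at the lower region and from both replicates at the upper. The region at Npas4 lay within the gene on chromosome 19 at 4992001 to 4993000. That at Nr4a3 lay 96.1 kb below its gene span, near the limit of 100 kb. With genes assigned up to 50 kb, 5 immediate early genes had gained regions, against 0.703 in random lists (adjusted permutation p = 0.009).

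Late activity-regulated genes, a later wave of genes induced by activity, had gained regions at 2 of 24 tested members in CTX, Acan and Plk2, and the list did not pass (adjusted permutation p = 1.0). The called length at Acan was 2.26 ± 0.485 and 0.384 ± 0.543 kb, and at Plk2 4.81 ± 1.39 and 4.47 ± 1.04 kb. Bdnf, the gene of a neurotrophin, had 3 gained single bins and no gained region, with 4.52 ± 1.81 kb called with KCl and 1.58 ± 1.06 kb without. Scg2, which encodes a secretory granule protein, had 3 single bins and 3.58 ± 0.819 against 1.21 ± 0.609 kb, and Nptx2, a secreted pentraxin, had 1 single bin and 2.18 ± 1.95 against 1.29 ± 1.43 kb. With single bins counted, late genes passed in CTX, at 20 of 24 genes against 9.96 in random lists (adjusted permutation p = 0.003). They also passed this permutation test without KCl replicate 1 (12 genes, adjusted p = 0.015) and without unstimulated replicate 2 (11 genes, adjusted p = 0.012). Outside the activity lists, the genes with most gained bins were Dlg2, a postsynaptic scaffold gene, with 8 bins, and Babam2, Gm4868, Jcad, Lrrc7, Pde10a, Pde4d and Polq with 4 bins each. Lost bins were most numerous at Rbfox3, the gene of the neuronal antigen NeuN, with 5, and at Acot11, D430019H16Rik, Gjb5 and Plb1 with 4 each. Lost regions touched 0 of 27 immediate early, 0 of 24 late and 0 of 10 GABAergic candidate genes. Random lists gave only 0.465, 0.434 and 0.129, so these zeros say little about the lists.

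The CTX counts depended on how much each library called. The split of the CTX libraries by replicate number gave 665 regions called only in replicate 2, more than the 386 gained, and the crossed splits gave 12 and 11. With the same number of called bases in every library, an alternative added after seeing the data, 546 regions were gained and 581 lost, so that gained regions made up 48.4% in place of 62.6%. The counts were 725 gained and 809 lost without KCl replicate 2, 458 and 2813 without unstimulated replicate 1, 3017 and 272 without KCl replicate 1, and 2103 and 437 without unstimulated replicate 2. By the permutation test, the call of the immediate early list was lost at a −log10 q of at least 5 (3 genes against 1.03 expected, adjusted p = 1.0), with equal numbers of peaks (6 against 1.62, adjusted p = 0.144) or equal called bases (5 against 1.32, adjusted p = 0.162), and within 2 kb of gene ends (2 against 0.359, adjusted p = 0.623). It was also lost without KCl replicate 1 (11 against 5.42, adjusted p = 0.16) and without unstimulated replicate 2 (10 against 4.67, adjusted p = 0.204), in the same permutation test. Within 2 kb of gene ends only 14 of the genes could be tested. Over all alternatives the adjusted permutation p of this list ranged from 0.006 to 1.0.

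**Figure D1:**
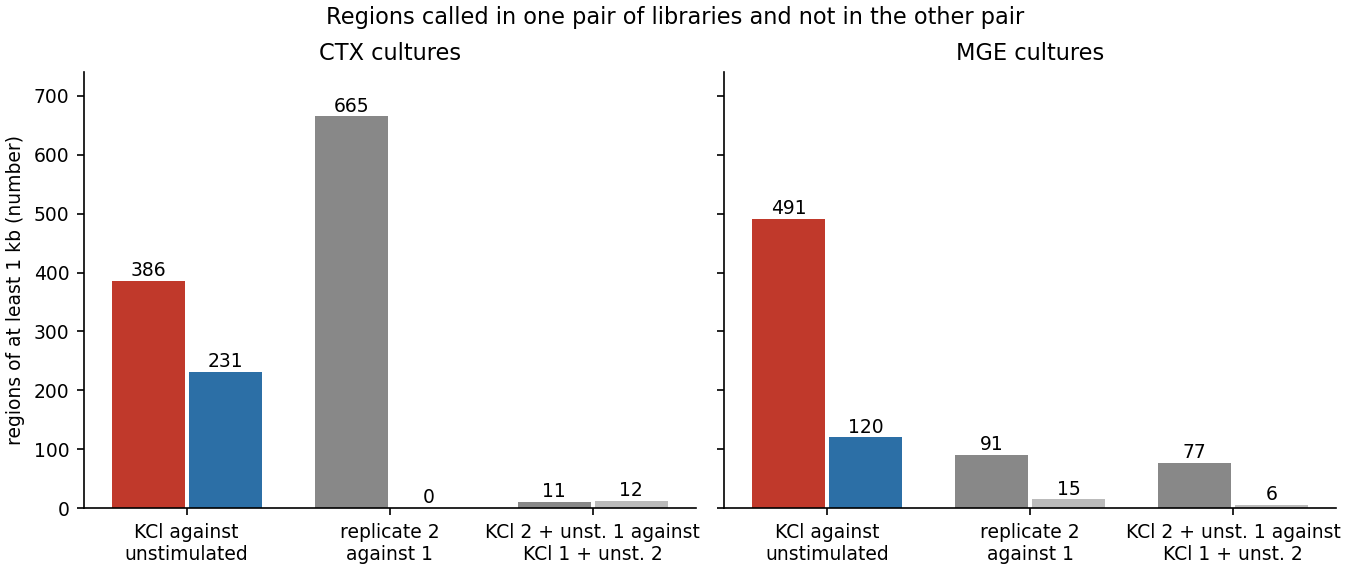
Number of regions of at least 1 kb called in both libraries of one pair and in neither of the other pair, for the 3 ways of pairing the 4 libraries of each culture; red bars are gained and blue bars lost with KCl, grey bars the control splits. In CTX the 386 gained regions stand below the 665 of replicate 2 alone, and in MGE the 491 gained regions stand above all control splits, of which the highest is 91.

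In MGE cultures, 491 regions were gained with KCl and 120 were lost. Gained regions lay at 10 of 23 tested immediate early genes, against 0.971 in random lists (one-sided permutation p = 0.0001, the smallest possible, adjusted p = 0.006). The 10 were Fos, Fosb, Fosl2, Atf3 and Maff, all bZIP factor genes, the zinc finger factor Egr1, Npas4, Nr4a2, Sik1 and the stress response gene Gadd45b. The called length at Fos was 7.22 ± 1.53 kb with KCl and 2.84 ± 0.649 kb without, at Fosb 3.69 ± 0.283 and 0.547 ± 0.244 kb, at Egr1 1.39 ± 0.473 and 0.142 ± 0.200 kb, and at Npas4 3.91 ± 0.180 and 1.85 ± 0.199 kb. Bins of Nr4a2 held 2.10 ± 0.533 kb with KCl and no called base in either unstimulated library. The region at Npas4 had the coordinates given for CTX, and Atf3 had a region on chromosome 1 at 191183001 to 191184000, inside the region gained in CTX.

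Late activity-regulated genes had gained regions at 4 of 19 members in MGE, Pcsk1, Trib1, Bdnf and Lmna, against 1.05 in random lists (permutation p = 0.0153, adjusted p = 0.306). Pcsk1, which encodes a prohormone convertase, had 2.93 ± 0.0255 kb called with KCl and 1.58 ± 0.417 kb without. Bdnf had 1.69 ± 0.625 kb with KCl and none without. Its gained region lay within the gene on chromosome 2 at 109677501 to 109678500, where peaks were also called in all 4 CTX libraries. Scg2 had 2 gained single bins, with 4.67 ± 0.639 against 2.53 ± 0.0933 kb, and Nptx2 had 1, with 1.49 ± 0.849 against 0.402 ± 0.194 kb. Counting regions in the gene body and 20 kb to each side, the late list passed with 5 genes (adjusted permutation p = 0.015). It also passed this permutation test without KCl replicate 1 (12 genes, adjusted p = 0.01) and without unstimulated replicate 2 (6 genes, adjusted p = 0.048). The genes with most gained bins were the phosphodiesterase gene Pde4d with 9, Samd4 with 7, Igf1 with 6, Gpm6a and Vwa8 with 5, and Arl4d, Atxn1, B3galt1, Babam2 and Cacng5 with 4 each. Lost bins numbered 3 each at Ablim1, Erbb4, Glis1, Glycam1 and Klhl6. Lost regions touched 0 members of the 3 activity lists, against 0.24 immediate early, 0.299 late and 0.18 candidate genes in random lists.

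In MGE the control splits gave at most 91 regions. Over all bins, not only runs of 2, the ratio of gained to lost was 2.17, against 4.09 for regions. With equal called bases 420 regions were gained and 303 lost, and gained regions made up 58.1% in place of 80.4%. The counts were 2846 gained and 215 lost without KCl replicate 1, 952 and 543 without KCl replicate 2, 1041 and 566 without unstimulated replicate 1, and 735 and 780 without unstimulated replicate 2. Between same-numbered libraries, 24.6% of called bins were called only with KCl and 29.6% only without in replicate 1, while replicate 2 had 44.0% and 14.4%. The immediate early call was lost only at a −log10 q of at least 5, among the alternatives run (5 genes against 2.01 expected, adjusted p = 1.0), and its adjusted permutation p otherwise lay between 0.003 and 0.006.

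Igf1, the gene of insulin-like growth factor 1, was among the candidates for activity regulation in GABAergic neurons. In MGE it gained regions on chromosome 10 at 87798001 to 87799000, 59.3 kb below the lower end of the gene span, and at 87859001 to 87861000, within the gene near that end. The called length at Igf1 was 7.84 ± 2.08 kb with KCl and 4.04 ± 0.837 kb without in MGE, and 2.38 ± 1.44 and 0.820 ± 0.322 kb in CTX, where 2 single bins and no region were gained. Of the candidates, Igf1, Crhbp and Nptx1 had gained regions in MGE, 3 of 8 against 0.645 in random lists (permutation p = 0.023, adjusted p = 0.345), and 0 of 10 had in CTX. Tested as a difference between cultures, 3 candidates were gained in MGE alone and 0 in CTX alone (exact McNemar p = 0.25, adjusted p = 1.0). For immediate early genes 5 members were gained in both cultures, 1 in CTX alone and 4 in MGE alone (p = 0.375, adjusted p = 1.0), and for late genes 0, 2 and 4 (p = 0.688, adjusted p = 1.0), by the same exact test. At most 6 genes differed in any list, for which the smallest exact p is 0.0312 before adjustment, so no list could have passed. With single bins counted, 6 of 10 candidates were gained in CTX and 6 of 8 in MGE, and of those tested in both cultures 2 were gained in CTX alone, 3 in MGE alone and 3 in both, Igf1 and Crhbp among them (exact McNemar p = 1.0). The candidates passed in MGE with regions in the gene body and 20 kb to each side (3 genes, adjusted permutation p = 0.0255), and not under the other alternatives.

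**Figure D2:**
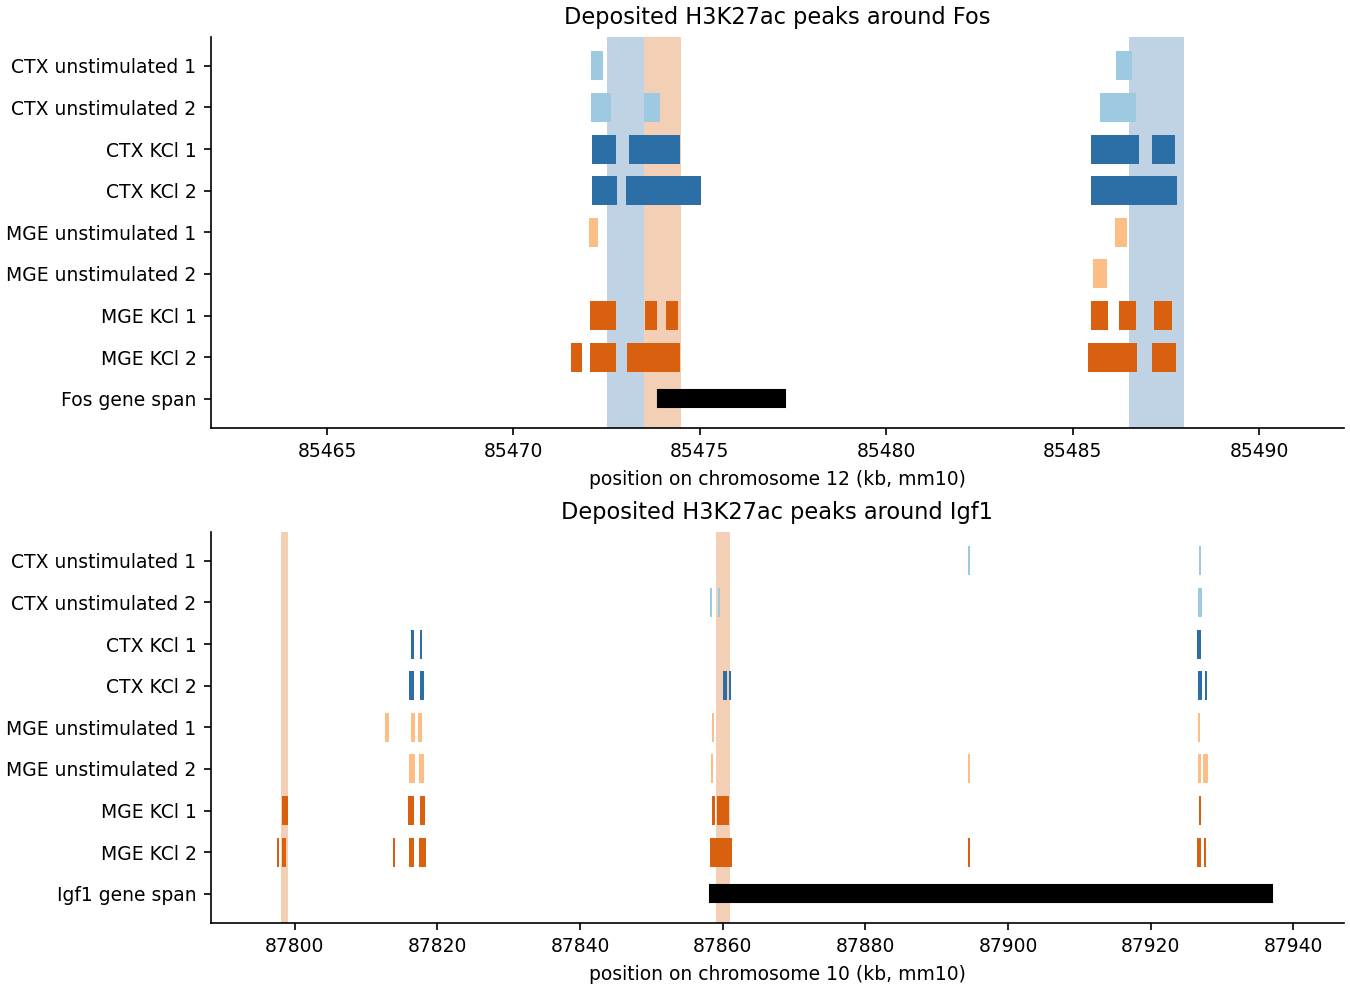
Deposited peaks around Fos and Igf1 in the 8 libraries (rows), by position in kb on mm10; shaded spans are gained regions, blue for CTX and orange for MGE, and the black bar is the gene span. The Igf1 span shaded at 87798001 holds peaks in both MGE KCl libraries and in no other library.

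Peak coverage gave the same lists a value per library, by a measure chosen after seeing the data. Immediate early genes held 1529 ± 196 bp of peaks per Mb called in CTX KCl and 893 ± 47.0 in CTX unstimulated cultures, a ratio of 1.71, and 1566 ± 87.4 against 626 ± 53.7 in MGE, a ratio of 2.50 (SD, n = 2). Late genes held 1235 ± 193 against 881 ± 22.5 in CTX and 1542 ± 152 against 1071 ± 1.76 in MGE, ratios of 1.40 and 1.44. For both lists each KCl library exceeded both unstimulated libraries of its culture, which gives the smallest p of the exact test within cultures, 0.0556 (adjusted p = 0.278). The GABAergic candidates had ratios of 0.921 in CTX and 1.65 in MGE (exact p = 0.333, adjusted p = 0.455), and at a −log10 q of at least 5 the ratios turned to 1.60 in CTX and 0.844 in MGE. Housekeeping genes had ratios of 1.12 in CTX and 1.01 in MGE, and endothelial and mural genes 0.615 and 0.735 (exact p = 0.0556, adjusted p = 0.278). Astrocyte genes had ratios of 1.33 and 1.51, CGE interneuron genes 1.24 and 1.40, LGE and striatal genes 1.22 and 1.3, and progenitor genes 1.12 and 1.54. The exact p of these lists ran from 0.111 to 0.389. Further lists lay nearer 1 or changed direction between cultures. MGE and GABAergic identity had 1.05 and 1.06, and synaptic and channel genes 0.984 and 1.15. Oligodendrocyte lineage genes had 1.29 and 0.646, and microglia genes 1.08 and 0.597. Ratios near those of late genes thus also occurred at astrocyte and CGE interneuron genes, and no test compared the lists.

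**Figure D3:**
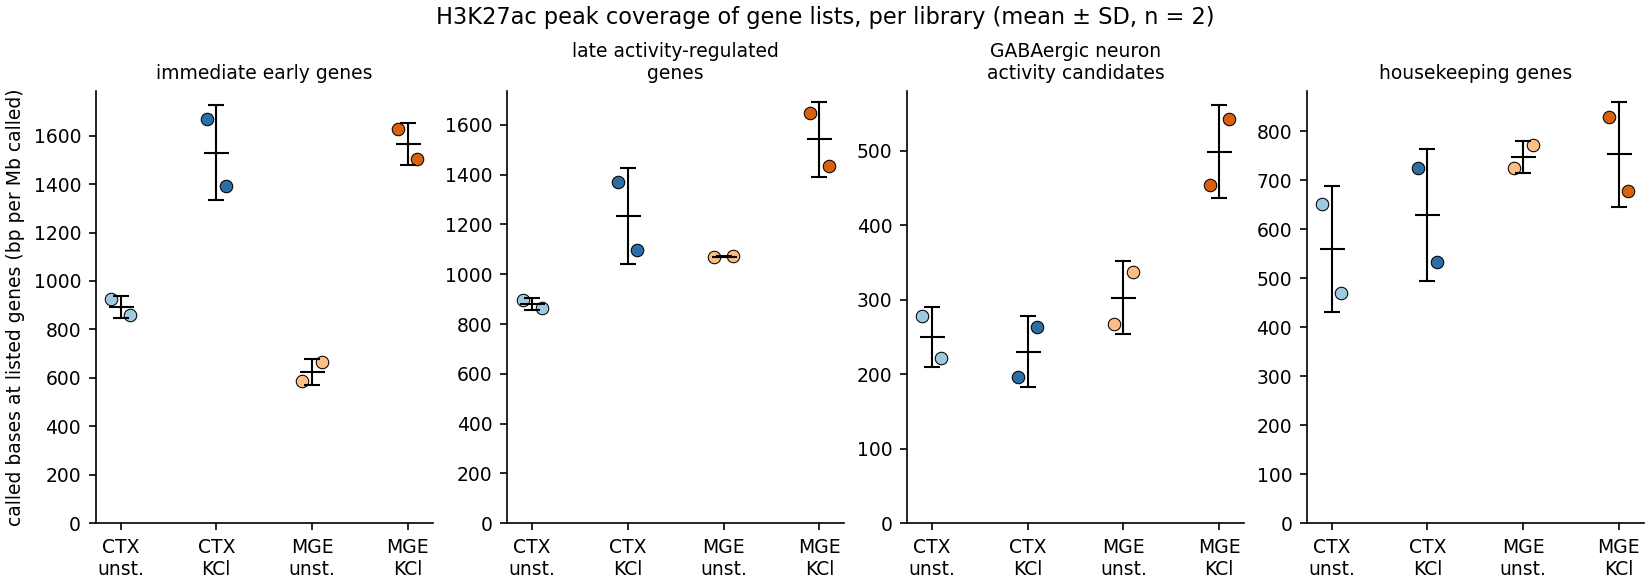
Called bases in listed genes and 2 kb to each side, in bp per Mb called, for each library (points) with the group mean and SD (bars, n = 2). Immediate early genes have means of 893 and 1529 in CTX and 626 and 1566 in MGE without and with KCl.

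The gained bins of both cultures coincided more often than independent lists would. Among 53329 bins called in at least 1 library of each culture, 986 were gained in both, against 314.5 expected, a ratio of 3.14 ± 0.0701 (SE over chromosomes). Lost bins had a ratio of 4.87 ± 0.328, with 184 shared against 37.8 expected. Bins gained in CTX and lost in MGE numbered 38 against 109.8 expected, and the opposite combination 19 against 108.2. Bins called only in replicate 2 of both cultures had a ratio of 1.21 ± 0.0860, and those called only in replicate 1 of both 4.53 ± 2.09, from 4 bins against 0.883 expected. The combinations of replicate 1 alone in one culture with replicate 2 alone in the other had ratios of 1.76 ± 0.459 (8 bins) and 1.47 ± 0.257 (41 bins). The genes with most bins gained in both were Pde10a, a striatal phosphodiesterase gene, with 4, and Acan, Fos, Mef2c, Myof, Npas4, Pde4d and Polq with 3 each. At Mef2c, a transcription factor gene of activity-dependent synapse control, the called length was 21.4 ± 5.06 kb with KCl and 13.9 ± 5.98 kb without in CTX, and 16.5 ± 3.95 and 10.3 ± 2.20 kb in MGE. At Pde10a it was 15.3 ± 4.39 and 9.68 ± 4.37 kb in CTX, and 10.2 ± 2.57 and 6.41 ± 0.297 kb in MGE. Across both cultures, 30 regions were called in all 4 KCl libraries and in no unstimulated library, Atf3 and Npas4 among them, and 2 regions the reverse. The 4 libraries with most called bases, 3 from CTX and 1 from MGE, shared 51 regions found in none of the other 4, and 0 the reverse, so the number alone does not set treatment apart from the bases called.

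Gained and lost regions lay in different places relative to genes. Within 2 kb of a gene end lay 30.1% ± 2.76 of gained regions in CTX and 29.7% ± 1.65 in MGE (SE over chromosomes). Of lost regions, 4.33% ± 1.27 and 7.50% ± 2.92 lay there. Regions called in all 4 libraries of a culture did so for 58.1% ± 1.2 in CTX and 58.7% ± 1.01 in MGE, and regions of replicate 2 alone for 16.8% ± 1.75 and 23.1% ± 5.60. Outside genes lay 31.3% of gained and 58.0% of lost regions in CTX, and 29.3% and 40.0% in MGE. No peak of the opposite treatment touched 54.1% of gained and 58.9% of lost regions in CTX, and 56.4% and 48.3% in MGE. A peak of the opposite treatment touched the others.

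Between cultures, 275 regions were called in all 4 MGE and no CTX library, and 469 in all 4 CTX and no MGE library. MGE-only regions lay at 4 of the 22 tested genes of MGE and GABAergic identity, Maf, Erbb4 and Gad2 among them, against 0.946 in random lists (one-sided permutation p = 0.0138, adjusted p = 0.207). Gad2 encodes an enzyme that makes GABA, Maf is a transcription factor gene of interneurons from the MGE, and Erbb4 is a receptor gene of interneurons. The called length at Maf was 6.55 ± 0.811 kb in MGE and 0.943 ± 0.395 kb in CTX (SD, n = 4, as for the values per culture below), at Erbb4 20.7 ± 4.39 and 9.69 ± 1.90 kb, and at Gad2 5.96 ± 1.58 and 3.35 ± 1.41 kb. The region at Gad2 lay within the gene on chromosome 2 at 22622501 to 22623500, and a peak of CTX unstimulated replicate 2 touched it. CTX-only regions lay at Tiam2, Zbtb18 and Tbr1, 3 of 24 genes of cortical glutamatergic identity (adjusted permutation p = 1.0), of which Tbr1 and Zbtb18 encode transcription factors of cortical projection neurons. The called length at Tiam2 was 13.5 ± 4.45 kb in CTX and 2.07 ± 0.794 kb in MGE, at Zbtb18 8.06 ± 3.14 and 0.430 ± 0.545 kb, and at Tbr1 1.84 ± 1.05 and 0.393 ± 0.167 kb. Sox6, a factor gene listed under MGE identity, had CTX-only regions in 6 bins and 22.5 ± 8.63 kb called in CTX against 12.8 ± 4.49 kb in MGE.

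Outside the identity lists, MGE-only bins were most numerous at Tox2 with 8, Slc44a5 and Tiam1 with 6, Blm, Cadps2, Gm4868 and Kcnma1 with 5, and Aadat with 4. The called length at Tox2 was 14.6 ± 2.07 kb in MGE and 5.49 ± 2.73 kb in CTX, and at Slc44a5 12.6 ± 1.10 and 3.62 ± 1.26 kb. CTX-only bins were most numerous at Arpp21, a cAMP-regulated phosphoprotein gene of forebrain neurons, with 11, at Scfd2 and Stk32a with 7, and at Fgf12, Lhfpl3, Lrp1b, Nfia and Notch1 with 6. Arpp21 held 17.2 ± 5.19 kb in CTX and 2.15 ± 0.774 kb in MGE, and Stk32a 6.93 ± 0.540 and 1.21 ± 0.816 kb. CTX-only regions were also assigned to 3 of 9 oligodendrocyte lineage genes, Olig1, Olig2 and Pdgfra, against 0.351 in random lists (permutation p = 0.0034, adjusted p = 0.102). In the gene body and 20 kb to each side, 0 of the 9 genes had such a region, against 0.170 in random lists. These 3 calls therefore rest on more distant regions. Of the identity and oligodendrocyte lists, some passed the permutation test under alternatives: MGE identity with 4 genes in the gene body and 20 kb to each side (adjusted p = 0.036) and with 7 genes without MGE unstimulated replicate 2 (adjusted p = 0.015), and oligodendrocyte genes with 6 without CTX unstimulated replicate 1 (adjusted p = 0.003). The CTX-only count was 980 without CTX KCl replicate 1 and 1032 without CTX unstimulated replicate 1, and the MGE-only count 431 without MGE unstimulated replicate 2.

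By coverage, genes of MGE and GABAergic identity held 2792 ± 159 bp per Mb called in MGE and 1973 ± 81.3 in CTX cultures, a ratio of 1.42, and genes of cortical glutamatergic identity 1630 ± 57.9 and 2096 ± 276, a ratio of 0.778. Markers of other cell types moved with the same comparison. Astrocyte genes held 365 ± 173 in MGE and 1460 ± 307 in CTX, oligodendrocyte lineage genes 161 ± 46.4 and 463 ± 110, neural progenitor genes 229 ± 129 and 649 ± 44.1, and microglia genes 121 ± 37.9 and 14 ± 11.5. For these 6 lists all 4 libraries of one culture lay above all 4 of the other (exact permutation p = 0.0286, adjusted p = 0.0714 each), which misses the threshold after adjustment and is the smallest p this design allows. Endothelial and mural genes held 164 ± 34.0 and 168 ± 48.1 (exact p = 0.886, adjusted p = 0.886). Among lists that mark no cell type, housekeeping genes had a ratio of MGE to CTX of 1.26 and late genes of 1.235. Synaptic and channel genes had 1.04 and immediate early genes 0.905. Over the alternatives run, the ratio of MGE and GABAergic identity ran from 1.17 to 1.49. No test compared the lists. The microglia values rest on 0 to 1156 called bases in a CTX library and 1830 to 3860 in an MGE library.

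**Figure D4:**
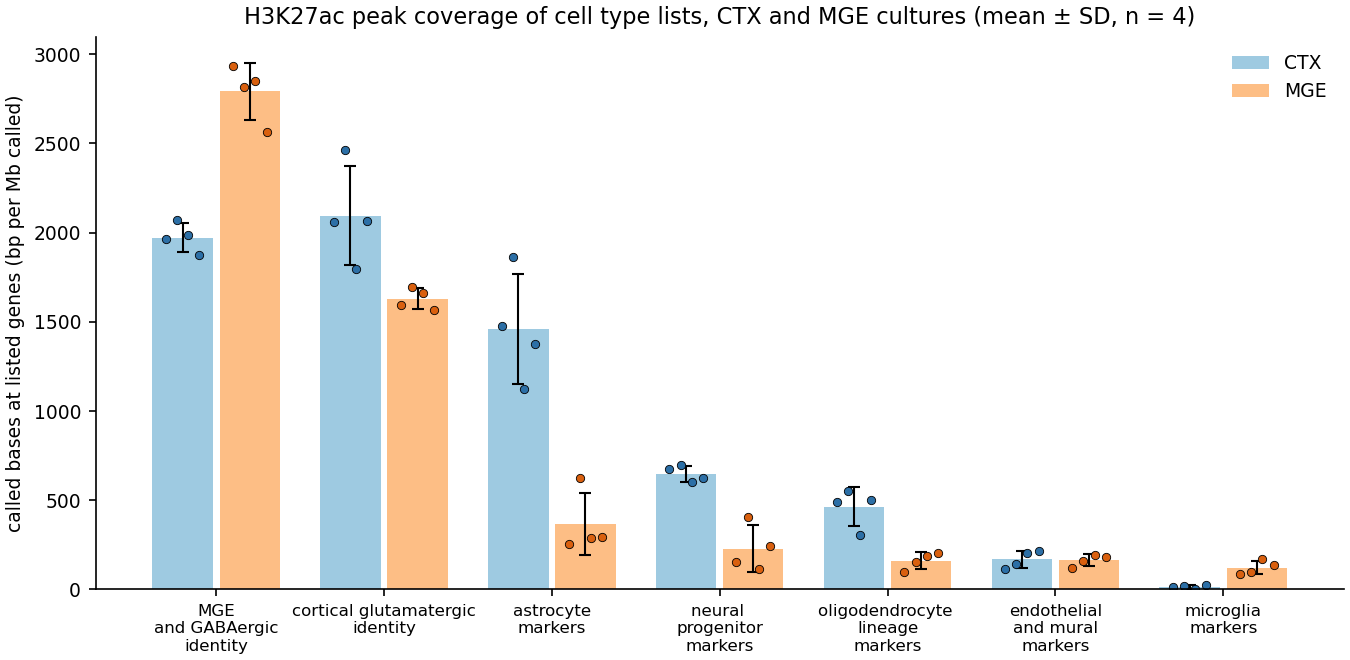
Called bases in listed genes and 2 kb to each side, in bp per Mb called, for 7 cell type lists; bars are means of the 4 libraries of a culture with SD, and points are libraries. Astrocyte, progenitor and oligodendrocyte lists are lower in MGE, with ratios of 0.250, 0.353 and 0.348 to CTX.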

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

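The setting with equal called bases, and every coverage ratio, was chosen after seeing the data. With a −log10 q of at least 5, CTX had 95 lost regions, MGE 820 gained and 181 lost, 135 regions were MGE-only and 285 CTX-only, and 636 bins were gained in both cultures. With equal numbers of peaks there were 603 gained and 441 lost regions in CTX and 190 lost in MGE, and with equal called bases 581 lost in CTX and 303 lost in MGE. In the order CTX gained, CTX lost, MGE gained, MGE lost, MGE-only, CTX-only and bins (or merged peaks) gained in both, the counts were 83, 33, 129, 24, 61, 121 and 411 with bins of 1 kb, 3347, 2245, 3279, 1338, 1849, 3494 and 1671 with any overlap, and 5410, 3729, 5176, 2463, 3041, 5491 and 638 with merged peaks. By construction larger bins admit fewer regions, and overlap admits more. Unstimulated libraries alone gave 881 MGE-only and 2001 CTX-only regions, and KCl libraries alone 1007 and 1861. Leaving out each library gave, in the same order of counts, 458 to 3017, 272 to 2813, 735 to 2846, 215 to 780, 278 to 431, 482 to 1032 and 1085 to 2183, since fewer libraries then have to meet the rule. Bins gained in both cultures exceeded the number expected in every alternative run, by ratios from 2.07 to 3.98.

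Of the lists tested by gained regions, the immediate early list lost its call in CTX with a −log10 q of at least 5 (3 genes), equal numbers of peaks (6), equal called bases (5) and a limit of 2 kb from gene ends (2). With a library left out it had 6 to 11 genes, and lost its call without KCl replicate 1 (11 genes) and without unstimulated replicate 2 (10 genes). In MGE it lost its call with a −log10 q of at least 5 (5 genes). Late genes passed in CTX with single bins (20 genes) and in MGE with gene bodies and 20 kb (5 genes). With a library left out they had 3 to 12 genes in CTX and 4 to 12 in MGE, and passed in 2 of the 4 cases in each culture. With gene bodies and 20 kb the GABAergic candidates in MGE (3 genes) and MGE identity (4 genes) passed too, while the oligodendrocyte list had 0 genes. Leaving out a library gave 4 to 7 genes for MGE identity and 3 to 6 for the oligodendrocyte list. The adjusted permutation p ranged over alternatives from 0.003 to 1.0 for late genes in CTX, 0.01 to 1.0 for late genes in MGE, 0.0255 to 1.0 for the GABAergic candidates, 0.015 to 1.0 for MGE identity and 0.003 to 1.0 for the oligodendrocyte list. The cause of these changes was not tested. Of the coverage ratios, that of the GABAergic candidates in MGE turned from 1.65 to 0.844 at a −log10 q of at least 5. Of the others, 133 values moved by less than the replicate SD and 11 by more, among them that of the GABAergic candidates in CTX, 1.60 at a −log10 q of at least 5 in place of 0.922. At that setting the ratios of MGE to CTX were 0.0701 for astrocyte, 0.171 for progenitor and 0.225 for oligodendrocyte genes, and with equal numbers of peaks the microglia ratio was 14. The microglia ratio has no value at a −log10 q of at least 5 or with equal called bases, where no base was called at these genes in CTX.

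The replicate numbers are shared by all groups, and deviations of same-numbered libraries correlated at −0.0350 in CTX and 0.0409 in MGE over bins. This correlation takes out the mean difference between replicates, so it cannot show same-numbered libraries that call more bases together. In CTX, 665 regions were called only in replicate 2 and 0 only in replicate 1. The numbers were not taken to pair the libraries, and whether they do stays open. The replicate block, a change within each same-numbered pair required in both pairs, is by construction the main rule and gave 386, 231, 491 and 120 regions and 986 bins. The motif tests were not run, nor were their 2 other settings. Read depth is unknown, so how many regions fell below the caller's threshold in the smaller libraries could not be estimated.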

Other observations

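The tests by coverage and those on the splits, the balance of gained and lost regions and the astrocyte and oligodendrocyte gene count were chosen only after their results, or results close to them, were seen. That gene count replaced a first version with fewer genes, all of them higher in CTX. Markers of CGE interneurons, a second GABAergic class, had gained regions at Reln and Ndnf in MGE, 2 of 7 (adjusted permutation p = 0.756), and at 0 of 9 in CTX. Their coverage was 735 ± 199 bp per Mb called in MGE and 795 ± 167 in CTX (SD, n = 4, exact p = 0.657). LGE and striatal genes held 833 ± 168 in MGE and 1253 ± 233 in CTX (exact p = 0.0571, adjusted p = 0.0952). Synaptic and channel genes had gained regions at Camk2a, Gria1 and Grin2a in MGE, 3 of 24 (adjusted permutation p = 1.0), and at 0 of 24 in CTX, with a coverage of 4259 ± 416 in MGE and 4083 ± 64.6 in CTX (SD, n = 4, exact p = 0.571). Housekeeping genes had gained regions at 0 of 7 in CTX and 0 of 8 in MGE, with a coverage of 750 ± 64.7 in MGE and 594 ± 115 in CTX. CTX-only regions lay at Nfia and Nfib, 2 of 10 astrocyte genes (adjusted permutation p = 0.986), and at Notch1, 1 of 12 progenitor genes, and at 0 of 2 microglia genes. Genes silent in neurons held 2.44 ± 4.88 and 16.4 ± 11.6 bp per Mb called. Lost regions lay at Flt1, 1 of 4 endothelial and mural genes tested in CTX (adjusted permutation p = 0.826).

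Beside Atf3, Npas4, Pde10a, Polq, Vwa8 and Babam2, the 30 regions called in all 4 KCl and no unstimulated library included 1 each at Nfatc2, a calcium-regulated transcription factor gene on chromosome 2 at 168609001 to 168610000, at Lef1, a factor gene of Wnt signalling on chromosome 3 at 131138501 to 131139500, and at the kinase gene Rps6ka5 on chromosome 12 at 100575501 to 100576500. These were picked after their positions were seen. Perfectly split regions were counted for the 35 splits of the 8 libraries into 4 and 4. The split by culture gave 744, and the highest other split gave 51. Only 1 split, the real one, reached 744, which is the best rank that 35 splits allow. As this count was chosen after its result, or one close to it, was seen, it does not exclude chance. A technical difference between the cultures was not tested by it.

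Gained regions outnumbered lost ones in both cultures, and in 3 of the 4 same-numbered pairs the KCl library called more bases. With the same number of called bases in every library the ratio of gained to lost regions was 0.940 ± 0.0804 in CTX (SE over chromosomes), from 1.67, and 1.39 ± 0.136 in MGE, from 4.09 (2.17 over all bins). This SE holds no spread between libraries. Without each library in turn the ratio with equal called bases ran from 0.545 to 1.51 in CTX and from 0.573 to 1.94 in MGE. It lay above 1 whenever a KCl library was left out and below 1 whenever an unstimulated one was. A side with 1 library is easier to meet, so these ratios follow the side that was cut and cannot decide the question. With all libraries, MGE kept more gained than lost regions and CTX did not, without a measure of the spread between libraries. A biological surplus of gained acetylation and more bases called with KCl therefore cannot be told apart in either culture.

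Astrocyte and oligodendrocyte genes were covered less in MGE than in CTX, while microglia genes had a ratio of 8.66 of MGE to CTX and endothelial and mural genes of 0.977. More called bases in CTX libraries do not account for it, since with equal called bases the astrocyte ratio was 0.200. A larger share of astrocytes and oligodendrocyte lineage cells in the CTX cultures is a candidate explanation: 20 of the 24 astrocyte and oligodendrocyte genes had more called bases per Mb in CTX, 1 (Mog) had more in MGE and 3 had none. In CTX coverage was highest at Nfia (795 ± 181 in CTX, 113 ± 73.7 in MGE) and Nfib, which neurons also express, and without both the astrocyte ratio rose from 0.250 to 0.441, while Cspg4 held 93.3 ± 9.13 in CTX and no called base in MGE. No cell sort is named in the labels, and a difference between cortical and MGE neurons themselves, or in embryonic age, was not tested and stays open.

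Igf1 gained regions in MGE and none in CTX, where it gained 2 single bins at other places, with 0 bins gained in both cultures. Peaks that narrowly missed the rule in CTX could account for this. Of the 6 Igf1 bins gained in MGE, 2 had a peak in a CTX KCl library, in replicate 2 alone. As many, 2, had a peak in CTX unstimulated replicate 2. The called length was higher with KCl in both cultures, 2.38 ± 1.44 against 0.820 ± 0.322 kb in CTX and 7.84 ± 2.08 against 4.04 ± 0.837 kb in MGE. The explanations cannot be told apart with 2 libraries per group. CTX libraries called more bases in total than MGE libraries of the same treatment and number. A total does not measure the yield at Igf1, so it does not decide whether peaks there fell below the threshold in CTX. A culture-specific response at Igf1 stays a hypothesis. For the 3 candidates that differed by regions, the exact McNemar p of 0.25 is the smallest possible, so that test could not decide it. With single bins counted, Igf1 and Crhbp were gained in both cultures, and 2 candidates were gained in CTX alone against 3 in MGE alone (exact p = 1.0).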
